A study of Prunus mume with 9 samples.

How the data were processed

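RNA-seq libraries of pistils taken from flower buds of Prunus mume (Japanese apricot) cultivar Daqiandi were analysed. Per the labels, Daqiandi pistils abort, and 3 stages of abortion were sampled with 3 libraries each. The stages are called here STYB, in which the style browns, STIB, in which the stigma browns, and OVB, in which the ovary browns. Per the labels' protocols, libraries were made with the TruSeq RNA kit and sequenced on the BGISEQ-500 platform. Libraries of the normal pistils of cultivar Longyan, which the design text names as the control, were not analysed here. Per the submitters' processing notes, Bowtie2 2.2.5 and RSEM 1.2.8 were used. The genome build and the annotation release are not given in the sources used here. The authors deposited 1 table of FPKM values (fragments per kilobase of transcript and per 1e6 mapped fragments), 1 value per gene and library, with 2 decimals. The table's columns for the stigma browning stage are spelled STLB. They were matched through the sample descriptions, which give the STLB column names for the samples titled STIB. A set of 37858 transcript sequences was also deposited by the authors. Per the file headers, it gives each gene's product name, and it served here for names, lengths and GC content.

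The table lists 23560 genes, of which 21975 are RefSeq gene models and 1585 are models without a product name. Of the named genes, 4654 are called uncharacterized. The gene identifiers of 20468 genes occur in the RefSeq gene table of assembly ASM2933915v1. The assembly behind the deposited values is not known, so no coordinates are given. Genes are named here by their symbol and by the product name that the authors' sequence headers give. No gene is listed at 0 in every library. A further 1418 genes have a sequence and are not in the FPKM table. Genes that share an exact stretch of 100 bases with another gene (4727 of the listed genes) are called near copies, because fragments from them can be split between copies, and their values are uncertain.

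Read counts were not among the files, so depth was estimated from the steps between low FPKM values. In short transcripts of 300 to 700 bases, 1300 genes, a low FPKM (at most 1) was compared with whole multiples of the FPKM that 1 fragment gives, with 90 bases subtracted from each transcript for the effective length. Estimated depth was 23.2 to 26.3 (in 1e6 fragments) per library, a ratio of 1.13. The low values that stood for only a few fragments numbered 212 to 258 per library, and 97.4% to 99.6% of them lay within 0.1 fragment of a whole number. A random value lies there in 20% of cases. The depth and the 90 bases were chosen to make this share largest, so 20% is not its chance level. At these depths an FPKM of 1 in a transcript of effective length 1 kb stands for 23 to 26 fragments. RSEM shares fragments among isoforms, so whole counts were not recovered for all genes and no count model was used.

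Values were tested as log2(FPKM + 1). Genes at FPKM 1 or more in at least 3 of the 9 libraries were kept, which left 18309 genes and removed 5251. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes at low FPKM. All 9 libraries entered 1 linear model in limma 3.58.1 (R 4.3.3; lmFit, contrasts.fit, eBayes with trend), with no covariate, 6 residual degrees of freedom and 2.89 prior degrees of freedom. The 3 contrasts were STIB minus STYB, OVB minus STIB and OVB minus STYB. Tests were two-sided, with Benjamini-Hochberg adjustment over the 18309 genes of each contrast and a threshold of 0.05 on the adjusted p. Means are arithmetic means of FPKM ± SD over 3 libraries. The labels do not say that the libraries of a stage came from separate trees, so p-values measure only the spread between these samples, which may be technical.

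A total of 35 gene lists was fixed as patterns on product names: auxin, ethylene, gibberellin, abscisic acid, jasmonate, cytokinin, brassinosteroid, starch and sugar breakdown, sugar transport, pectin degradation, cell wall loosening, cellulose synthesis, lignin and phenylpropanoid, flavonoid, peroxidase and polyphenol oxidase, antioxidant, senescence and cell death, autophagy, NAC factors, WRKY factors, MADS-box factors, pistil and ovule development, cell cycle, DNA replication and histones, ribosomal proteins, photosynthesis, heat shock proteins, pathogenesis-related, cuticle and lipid, aquaporin, self-incompatibility, and 4 lists of markers of other tissues (pollen and anther, secondary wall and xylem, petal pigment, leaf and bract photosynthesis). Lists of 5 or more tested genes were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 34 testable lists within each contrast. The self-incompatibility list had 0 tested genes. For every list the members past the limma test are counted with adjustment over all genes and also adjusted over the list alone. Patterns on names take in some genes of another function. The cell cycle pattern also matches a cyclin-dependent kinase inhibitor and calcyclin-binding protein, the pectin degradation pattern matches polygalacturonase inhibitors, the starch pattern matches invertase inhibitors, the cytokinin pattern matches clock-associated response regulators, and the senescence pattern matches flap endonuclease. The petal list lies within the flavonoid list and the leaf list within the photosynthesis list. The patterns of the senescence and the secondary wall lists both match xylem cysteine proteinases. Those of the cellulose synthesis and the secondary wall lists share some cellulose synthase and COBRA-like names.

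Named genes were taken by a rule. In each contrast these were the 8 largest rises and the 8 largest falls among genes past the threshold with a mean FPKM of 5 or more in 1 stage, no overlap between the 3 values of either stage, and an informative product name. Added to them were up to 3 members with the smallest adjusted p from each list that moved or had 3 or more members past the test. The groups, the tests, the lists, this rule and most alternatives were set before the data were examined. The alternatives were pseudocounts of 0.1 and 5, no filter and a filter of FPKM 5, 3 other scalings (equal sums as in TPM, median ratio, quantile), the replicate number as a block, only the 2 stages compared, array weights, robust hyperparameters, a minimum log2 fold change of 1, and leaving out each library. For lists they were an estimated correlation, fry, the block, the low pseudocount and median ratio scaling. The exclusion of near copies, the list tests with each library left out and the list counts under each scaling were added after the data had been seen. The fits were tested on simulated data made from the real genes' means and spread with 200 genes changed by 1.5, 2 or 4 fold. At those sizes 44.8%, 73.1% and 93.9% of the changed genes were recovered for STIB against STYB, 32.8%, 67.2% and 89.4% for OVB against STIB, and 52.2%, 76.1% and 95.5% for OVB against STYB, with 0 of wrong sign and 4.7%, 3.1% and 5.1% of calls false. Only 200 of 18309 genes were changed there, with noise independent between genes, whereas the real contrasts called 41.1%, 55.9% and 52%. The simulated rates therefore need not hold for the real tests. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.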

Results

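Gene expression was measured by RNA-seq in pistils of flower buds of Japanese apricot (Prunus mume) cultivar Daqiandi, whose pistils abort per the labels. In each library PMADS 2, a gene of petals and stamens, had at least 7.7 times the FPKM of AGAMOUS. Tissue beside the pistil may therefore be present, and the changes below cannot be assigned to the pistil alone. The 9 libraries cover 3 stages of the abortion with 3 libraries each, named for the part of the pistil that browns: the style (STYB), the stigma (STIB) and the ovary (OVB). The comparisons ask which genes differ between the stages. Estimated depth was 23.2 to 26.3 (in 1e6 fragments) per library, with stage means of 24.9 for STYB, 24.1 for STIB and 26.2 for OVB. All expression values are the authors' FPKM, given as mean ± SD with n = 3 libraries per stage, and log2 changes are on the log2(FPKM + 1) scale. OVB stood farthest from the other stages. On the first principal component, with 61.8% of the variance, OVB libraries lay at 69.7 to 90.2 and the other 6 libraries between -46.7 and -35.2. The second component, with 21.4%, separated STYB (37.7 to 45.8) from STIB (-41.6 to -37.2). Pearson's r of log2 values across genes was 0.976 to 0.992 within a stage, 0.939 to 0.949 between STIB and STYB, and 0.85 to 0.897 between OVB and the other stages. OVB replicate 1 stood apart from the other OVB libraries on the third component (5.2% of the variance), at 32.8 against -18 and -19.3. The SD of the log2 differences was 0.446 and 0.422 between OVB replicate 1 and the other OVB libraries and 0.254 between those 2. Without OVB replicate 1, the limma test called 8189 genes for STIB against STYB, 9244 for OVB against STIB and 8553 for OVB against STYB.

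**Figure D1:**
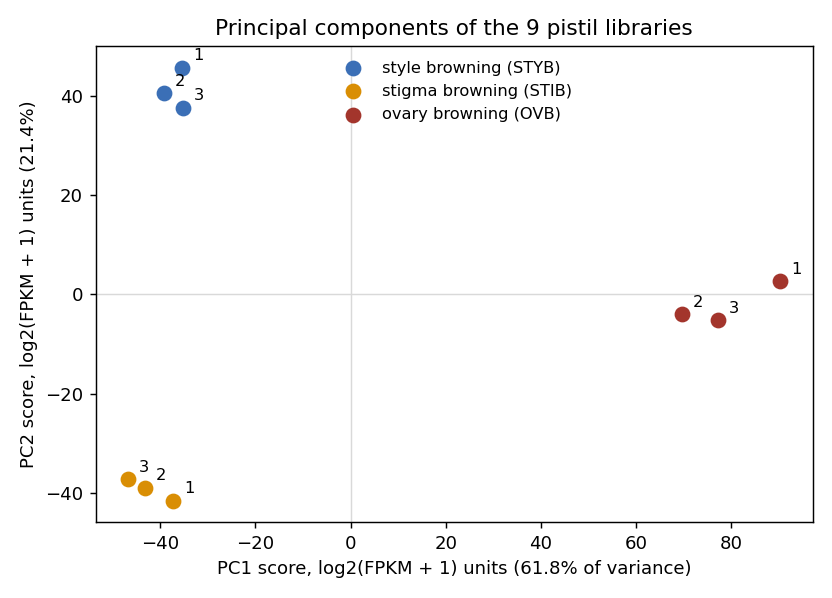
Principal components of log2(FPKM + 1) over the tested genes, with component 1 (61.8% of the variance) on the x axis and component 2 (21.4%) on the y axis. Each point is a library numbered by its replicate, and the 3 OVB libraries lie between 69.7 and 90.2 on component 1, above the other 6.

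The genes with the largest changes from STYB to STIB included 2 of wall proteins that rose and 2 of regulators of light or clock responses that fell. An extensin-like gene (LOC103324104), which codes for a structural wall protein, rose from 47.25 ± 11.3 to 1159 ± 273 FPKM (log2 change 4.59), and glycine-rich cell wall structural protein 2 (LOC103320464) from 10.05 ± 4.77 to 133.2 ± 34. Protein LNK3 (LOC103330811), a member of a family of clock-associated regulators, fell from 138.6 ± 9.53 to 8.45 ± 1.62 (log2 change -3.90), and zinc finger protein CONSTANS-LIKE 2 (LOC103329622), a B-box factor of light signalling, from 157.7 ± 20.7 to 20.35 ± 2.21. Of the 64 tested DNA replication and histone genes, 40 rose and 0 fell, with a median log2 change of 0.51 (camera adjusted p = 6.1e-06, and adjusted p = 0.94 with an estimated correlation). In the auxin list 30 of 95 members fell and 17 rose (camera adjusted p = 0.0102, and adjusted p = 0.81 with an estimated correlation). Among further large rises, purple acid phosphatase 17-like (LOC103338911) went from 1.92 ± 0.899 to 56.5 ± 11.7 FPKM, an L-ascorbate oxidase homolog (LOC103334886) from 6.68 ± 2.66 to 79.4 ± 10.1, and bidirectional sugar transporter N3 (LOC103322118), of the SWEET family of sugar exporters, from 1.04 ± 0.544 to 21.5 ± 8.58. Protein LIM1 (LOC103330527), a lipid-transfer-type protein, rose from 25.9 ± 11.6 to 316.2 ± 70.8. It belongs to a group of 18 tapetum and sporopollenin genes of anthers, put together after the results were seen, of which 12 rose and 0 fell. Whether the libraries hold stamen tissue was not known from the labels. Large falls included blue copper protein (LOC103329437), from 75.8 ± 6.11 to 7.74 ± 2.33, and CYP86A1 (LOC103320591), a fatty acid hydroxylase of suberin synthesis, from 162.2 ± 21.1 to 23.9 ± 4.88. B-box zinc finger protein 32 (LOC103327411) fell from 46.8 ± 5.31 to 4.81 ± 1.29. ERF027-like (LOC103337424), an ethylene-responsive transcription factor, fell from 15.4 ± 6.73 to 0.117 ± 0.202. The limma adjusted p of these genes ran from 9.2e-06 for LNK3 to 0.0059 for LIM1.

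The rise of histone genes at STIB included histone H2B.3 (LOC103339885), from 5.13 ± 0.404 to 34.7 ± 3.5 FPKM, histone H1.2 (LOC103334151), from 123.1 ± 7.7 to 284.6 ± 23.2, and histone H2AX (LOC103344700), from 115.7 ± 6.85 to 216.1 ± 9.19. Adjusted over the list alone, 41 of the 64 members passed. Under quantile normalization the list counted 35 members higher and 4 lower. Cell cycle genes went with them by count, 41 of 112 higher and 8 lower (50 adjusted over the list alone), but the list missed the threshold (camera adjusted p = 0.0537) and counted 30 higher and 16 lower under quantile normalization. Cyclin-D6-1 (LOC103329497) rose from 11.8 ± 0.77 to 23.7 ± 1.73, while cyclin-D3-2 (LOC103337458) fell from 74 ± 2.11 to 48.2 ± 2.57. Of 63 heat shock genes, 27 rose and 4 fell (33 adjusted over the list alone; camera adjusted p = 0.0329, and adjusted p = 0.81 with an estimated correlation). Heat shock cognate 70 kDa protein 2 (LOC103332638), a chaperone, rose from 64.4 ± 7.57 to 200.3 ± 31.6, and heat stress transcription factor B-2b (LOC103337430) from 7.82 ± 1.27 to 20.25 ± 1.63. Under quantile normalization 23 heat shock genes were higher and 7 lower. The heat shock call was lost without STYB replicate 3 (camera adjusted p = 0.0929) or without STIB replicate 1 (0.0962). In the senescence and cell death list, 9 of 14 members rose and 0 fell (9 adjusted over the list alone; camera adjusted p = 0.0337, and adjusted p = 0.81 with an estimated correlation). Its risers were nucleases, which degrade nucleic acids, and proteases including metacaspases, which act in plant cell death. Endonuclease 2 (LOC103341497) rose from 5.1 ± 2.21 to 15.7 ± 3.36 and bifunctional nuclease 1 (LOC103320881) from 16.65 ± 0.758 to 31.9 ± 1.15. Xylem cysteine proteinase 1 (LOC103334626), also a member of the secondary wall and xylem list, rose from 7.41 ± 1.76 to 15.7 ± 3.15. The senescence and cell death call was lost without STYB replicate 1 (0.0646), STYB replicate 3 (0.0736), OVB replicate 1 (0.059), OVB replicate 2 (0.0542) or OVB replicate 3 (0.052).

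The falls of the auxin list at STIB included auxin response factor 9 (LOC103337763), from 36.2 ± 3.34 to 14.3 ± 0.823 FPKM, and YUCCA4 (LOC103320034), an enzyme of auxin synthesis, from 7.96 ± 0.255 to 2.79 ± 0.394. Adjusted over the list alone 48 auxin genes passed. Of 27 pistil and ovule development genes, 7 fell and 2 rose (9 adjusted over the list alone; camera adjusted p = 0.0329, and adjusted p = 0.94 with an estimated correlation; fry adjusted p = 0.085). Under quantile normalization 11 fell and 2 rose. BEL1-like homeodomain protein 3 (LOC103321325) fell from 14.7 ± 0.743 to 7.14 ± 0.279, whereas WUSCHEL-related homeobox 13 (LOC103340316) rose from 5.45 ± 0.762 to 10.95 ± 0.678. Markers of other tissues differed as well between these libraries. The secondary wall and xylem markers had 11 of 21 members higher and 0 lower (11 adjusted over the list alone; camera adjusted p = 0.0276, and adjusted p = 0.94 with an estimated correlation). Fasciclin-like arabinogalactan protein 12 (LOC103325103) rose from 16.5 ± 3.22 to 42.35 ± 2.57, and the call was lost without STYB replicate 3 (0.0736). Of 12 pollen and anther markers 5 rose and 0 fell (5 adjusted over the list alone; camera adjusted p = 0.117), against 3 risers under median ratio scaling and 2 under quantile normalization. Pollen-specific protein C13 (LOC103332990) rose from 670.8 ± 69.3 to 1169 ± 22.9. Of 19 leaf and bract markers 7 fell and 0 rose (4 adjusted over the list alone; camera adjusted p = 0.121). A small subunit of ribulose bisphosphate carboxylase (LOC103323550) fell from 791.8 ± 163.8 to 248.4 ± 14.1. Of 11 petal pigment markers 4 rose and 1 fell (6 adjusted over the list alone; camera adjusted p = 0.761), against 2 and 2 under median ratio scaling and 3 and 2 under quantile normalization.

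The remaining lists did not pass camera between STIB and STYB, although single members changed. Among hormone genes, gibberellin 3-beta-dioxygenase 1-like (LOC103320029), which makes active gibberellin, fell from 67.8 ± 34.9 to 9.27 ± 1.93 FPKM, and 12-oxophytodienoate reductase 3 (LOC103340574), of jasmonate synthesis, rose from 65.4 ± 8.14 to 148.9 ± 31.4. Response regulator ARR5-like (LOC103338281), of cytokinin signalling, fell from 15.3 ± 2.97 to 3.62 ± 0.686. Members higher and lower numbered 22 and 28 of 109 for ethylene, 6 and 6 of 24 for gibberellin, 6 and 9 of 24 for abscisic acid, 13 and 4 of 41 for jasmonate, 9 and 10 of 33 for cytokinin and 2 and 2 of 8 for brassinosteroid (51, 12, 16, 18, 21 and 4 adjusted over the list alone). Among wall genes, xyloglucan endotransglucosylase 24-like (LOC103323436), a wall-remodelling enzyme, rose from 6.5 ± 2.44 to 44.6 ± 10.1, and cellulose synthase catalytic subunit 2 (LOC103331341) from 13.8 ± 0.895 to 34.7 ± 3.15. Wall loosening genes were higher in 18 and lower in 5 of 37, cellulose synthesis genes in 10 and 1 of 24, pectin degradation genes in 17 and 10 of 75, and lignin genes in 14 and 17 of 69 (25, 11, 27 and 32 adjusted over the list alone). Peroxidase-like protein 2 (LOC103335954) fell from 586.3 ± 33.4 to 116.9 ± 33.4, and WRKY22 (LOC103332064), a defence-related transcription factor, rose from 10.9 ± 3.3 to 49.8 ± 10.8. CUP-SHAPED COTYLEDON 1 (LOC103338789), an organ boundary factor, fell from 12.6 ± 2.76 to 1.69 ± 0.602. Members higher and lower were 10 and 10 of 46 for peroxidases and polyphenol oxidases, 23 and 14 of 86 for antioxidant genes, 10 and 5 of 43 for flavonoid genes, 11 and 14 of 52 for NAC, 15 and 14 of 52 for WRKY and 3 and 8 of 31 for MADS-box factors (20, 37, 14, 25, 30 and 11 adjusted over the list alone). They were 14 and 6 of 43 for starch and sugar breakdown, 12 and 8 of 40 for sugar transport, 3 and 4 of 22 for autophagy, 68 and 10 of 279 for ribosomal proteins and 4 and 10 of 51 for photosynthesis (21, 22, 7, 69 and 9 adjusted over the list alone). For pathogenesis-related genes they were 20 and 12 of 108, for cuticle and lipid genes 21 and 19 of 106, and for aquaporins 6 and 4 of 21 (27, 37 and 10 adjusted over the list alone). Under quantile normalization the balance turned for sugar transport (9 higher, 10 lower), WRKY (14 and 15) and cuticle and lipid genes (15 and 24, and 19 and 21 under median ratio scaling). It also became 5 and 12 for peroxidases and polyphenol oxidases (10 and 12 under median ratio scaling), 11 and 11 for pectin degradation, 3 and 10 for abscisic acid, 13 and 9 for jasmonate (11 and 7 under median ratio scaling) and 9 and 2 for cellulose synthesis (8 and 2). It became 8 and 7 for flavonoid genes under both scalings and 6 and 13 for cytokinin (7 and 11 under median ratio scaling), and the even splits of gibberellin and brassinosteroid became 5 and 6 and 2 and 3. Auxin counted 12 higher and 35 lower, ethylene 17 and 33, lignin 13 and 24, wall loosening 16 and 7 and autophagy 2 and 5. Of the 34 tested lists, the share of higher members among those that passed was smaller in 28 under quantile normalization and larger in 1.

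In all, 7522 of 18309 genes (41.1%) differed between STIB and STYB at a limma adjusted p under 0.05, 4473 higher (59.5%) and 3049 lower. Of these, 905 rose and 506 fell by at least 1 on the log2 scale. Quantile normalization called 7769 genes and turned the balance, with 3593 higher (46.2%) and 4176 lower. Medians, means and camera directions differed in sign for brassinosteroid (-0.03, 0.02, down), flavonoid (0.01, 0.18, down), antioxidant (0.05, 0.17, down), NAC (0.01, -0.015, down), WRKY (0.19, 0.2, down), photosynthesis (0.06, -0.09, down), cuticle and lipid (0.08, 0.06, down) and aquaporin (0.09, 0.13, down). The peroxidase and polyphenol oxidase list had a median of 0, a mean of 0.002 and a downward direction.

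From STIB to OVB, 55 of 64 DNA replication and histone genes fell and 1 rose, and 75 of 112 cell cycle genes fell and 11 rose. Camera called both lists (adjusted p = 7.4e-15 and 9.7e-09), with adjusted p = 0.61 and 0.78 with an estimated correlation. Flavonol synthase/flavanone 3-hydroxylase (LOC103332910), of flavonoid synthesis, rose from 52.5 ± 6.92 to 588.2 ± 71.8 FPKM (log2 change 3.46), and 1-aminocyclopropane-1-carboxylate oxidase (LOC103329345), the enzyme of the last step of ethylene synthesis, from 80.6 ± 2.22 to 504.1 ± 24.5. A transcription factor gene of the MYB family (LOC103329844) rose from 0.467 ± 0.293 to 146.5 ± 30.6 (log2 change 6.65). MADS-box protein AGL24-like (LOC103319497), of the family that holds the dormancy-associated MADS-box genes of Prunus, fell from 45.5 ± 4.49 to 0.2 ± 0.04 (log2 change -5.27). A putative cell wall protein (LOC103329545) went from 17.5 ± 4.71 to 1334 ± 279, alanine-glyoxylate aminotransferase 2 homolog 2 (LOC103343315), of mitochondrial amino acid metabolism, from 3.19 ± 0.312 to 260.5 ± 70.3, and a BURP domain protein (LOC103319959, a near copy) from 6.74 ± 2.84 to 1118 ± 257. An L-ascorbate oxidase homolog (LOC103319834) was listed at 0 in all STYB and STIB libraries and stood at 90.88, 63.26 and 51.8 FPKM in OVB replicates 1, 2 and 3. Among the falls, stearoyl-ACP desaturase 6 (LOC103336423), of fatty acid synthesis, went from 66.4 ± 10.7 to 0.197 ± 0.0231, late embryogenesis abundant protein D-29 (LOC103323300), of a stress-protective family, from 132 ± 4.19 to 2.36 ± 0.715, and the proline-rich protein DC2.15-like (LOC103331719) from 331.7 ± 59.7 to 4.89 ± 0.683. YLS3 (LOC103338843) fell from 290.6 ± 66 to 4.63 ± 5.85. LIM1 (LOC103330527) fell from 316.2 ± 70.8 to 6.84 ± 7.86 and protein 108-like (LOC103333418) from 1357 ± 190 to 54.2 ± 54.9, both of the tapetum and sporopollenin group, in which 12 of 18 genes fell and 3 rose. For YLS3, LIM1 and protein 108-like OVB replicate 1 was lowest, at 0, 0.26 and 0.31 FPKM, against 11.21, 15.54 and 110.13 in OVB replicate 2 and 2.69, 4.71 and 52.12 in OVB replicate 3. The limma adjusted p of the genes in this paragraph ran from 2.2e-07 for the MYB gene to 0.0044 for protein 108-like.

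Histone H4 (LOC103323029) fell from 337.8 ± 2.43 at STIB to 48 ± 8.87 FPKM at OVB, and H2B.3 (LOC103339885) from 34.7 ± 3.5 to 6.68 ± 0.618. Adjusted over the list alone 56 of the 64 members passed, and 88 of the cell cycle list. Cyclin-D6-1 (LOC103329497) fell from 23.7 ± 1.73 to 4.99 ± 0.917, and SMR3 (LOC103339534), an inhibitor of cyclin-dependent kinases, rose from 15.6 ± 2.27 to 97.9 ± 10.7. Of 43 flavonoid genes 25 rose and 6 fell (32 adjusted over the list alone; camera adjusted p = 0.000996, and adjusted p = 0.61 with an estimated correlation). Beside this list, 3 homeotic genes of petals and stamens, put together after the results were seen, rose as well: PMADS 2 (LOC103319765) from 605.7 ± 73.2 to 1211 ± 29.5, DEFICIENS (LOC103321303) from 29.1 ± 0.425 to 44.15 ± 2.92 and DEFICIENS-like (LOC103340165) from 217 ± 28 to 353.5 ± 3.22. AGAMOUS was higher too, at 59.27, 50.69 and 48.17 in the STIB libraries and 158.6, 118.49 and 145.82 in the OVB libraries. The ratio of PMADS 2 to AGAMOUS was thus lower at OVB (7.7, 9.9 and 8.4) than at STIB (11.6, 10.8 and 12.1). Of 69 lignin and phenylpropanoid genes 30 rose and 12 fell (43 adjusted over the list alone; camera adjusted p = 0.0246, and adjusted p = 0.92 with an estimated correlation). Laccase-4-like (LOC103338176), of lignin polymerisation, rose from 0.0967 ± 0.0551 to 21.1 ± 6.27, and the caffeic acid O-methyltransferase gene OMT1, a near copy, from 10.75 ± 2.39 to 215.5 ± 28.3. Antioxidant genes rose in 44 and fell in 12 of 86 (56 adjusted over the list alone; camera adjusted p = 0.00185, and adjusted p = 0.61 with an estimated correlation). Monodehydroascorbate reductase 4 (LOC103329845) rose from 10.6 ± 0.8 to 24.7 ± 2.04, and a glutathione S-transferase (LOC103325854), from 0.123 ± 0.15 to 4.29 ± 0.715. WRKY factors fell in 25 and rose in 5 of 52 (31 adjusted over the list alone; camera adjusted p = 0.014, and adjusted p = 0.93 with an estimated correlation). WRKY22 (LOC103332064) fell from 49.8 ± 10.8 to 2.63 ± 0.485 and WRKY7 (LOC103320368) from 40 ± 7.44 to 7.29 ± 1.51. Beside these groups, 7 of 11 petal pigment markers rose and 1 fell (8 adjusted over the list alone; camera adjusted p = 0.0868), and 6 of 19 leaf and bract markers rose and 1 fell (5 adjusted over the list alone; camera adjusted p = 0.236). Pollen and anther markers rose in 3 and fell in 6 of 12 (10 adjusted over the list alone; camera adjusted p = 0.469). Of these, major pollen allergen Ole e 6-like (LOC103334222) was listed at 0 in all STYB and STIB libraries and at 14.49, 7.12 and 6.53 in OVB replicates 1, 2 and 3. Secondary wall and xylem markers rose in 8 and fell in 10 of 21 (19 adjusted over the list alone; camera adjusted p = 0.787).

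**Figure D2:**
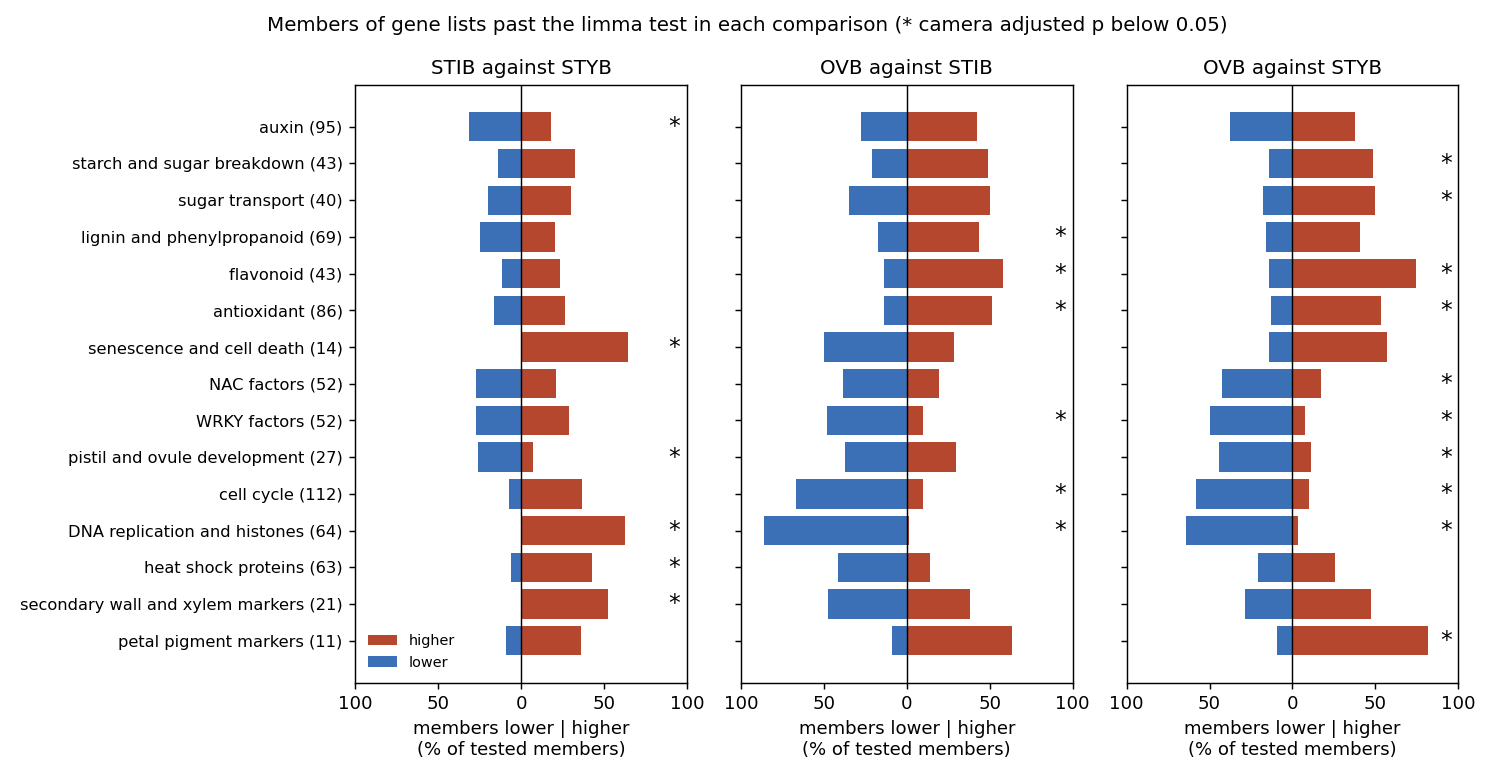
Members of 15 gene lists lower (left) and higher (right) in each comparison, in percent of the tested members, with 1 panel per comparison and a star at a camera adjusted p under 0.05. In OVB against STIB 55 of 64 DNA replication and histone genes were lower, and 25 of 43 flavonoid genes were higher.

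Sugar and wall genes showed some of the widest changes between STIB and OVB, although their lists did not pass camera. An insoluble beta-fructofuranosidase (LOC103341755), a cell wall invertase, rose from 0.847 ± 0.138 to 219.8 ± 228.2 FPKM, with 482.57, 71.43 and 105.29 in OVB replicates 1, 2 and 3. Putative invertase inhibitors rose as well, LOC103331457 from 0.92 ± 0.304 to 33.1 ± 0.447 and LOC103328886 from 0.717 ± 0.179 to 87.2 ± 52.8 (146.29, 44.81 and 70.5 in OVB replicates 1, 2 and 3). Polyol transporter 5-like (LOC103335555) rose from 93.9 ± 0.851 to 689.6 ± 66.5, whereas SWEET1 (LOC103336435) fell from 42.7 ± 5.02 to 7.53 ± 1.96. The counts higher and lower were 21 and 9 of 43 for starch and sugar breakdown and 20 and 14 of 40 for sugar transport (30 and 34 adjusted over the list alone). Polygalacturonase inhibitor (LOC103339521), which restrains pectin breakdown, rose from 9.93 ± 3.77 to 180.4 ± 22.4, and the pectin degradation list, which holds it, had 32 higher and 21 lower of 75 (53 adjusted over the list alone). Wall loosening genes were higher in 9 and lower in 21 of 37, and cellulose synthesis genes in 8 and 13 of 24 (31 and 21 adjusted over the list alone). Cellulose synthase-like protein D3 (LOC103333494) fell from 85.8 ± 8.26 to 30.1 ± 2.55. ECERIFERUM 1-like (LOC103331464), of wax synthesis and a near copy, rose from 0.977 ± 0.495 to 120 ± 54.6, within a cuticle and lipid list of 23 higher and 47 lower of 106 (70 adjusted over the list alone). Peroxidases and polyphenol oxidases were higher in 15 and lower in 16 of 46 (34 adjusted over the list alone). Polyphenol oxidase (LOC103324679, a near copy), which oxidises phenols to brown quinones, rose from 36.3 ± 3.28 to 515.8 ± 64.9, and peroxidase A2-like (LOC103327462) from 7.96 ± 1.75 to 128.9 ± 37.7.

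Hormone genes went both ways between STIB and OVB. Gibberellin 20 oxidase 1-like (LOC103331934), of gibberellin synthesis, rose from 12.9 ± 3.63 to 84.7 ± 2.73 FPKM, and gibberellin 2-beta-dioxygenase 8 (LOC103324491), which inactivates gibberellin, fell from 18.7 ± 3.27 to 0.493 ± 0.156. TIFY 6B-like (LOC103321427), of a family of jasmonate response repressors, rose from 80.2 ± 4.45 to 411.1 ± 26.6, and auxin-induced protein 15A-like (LOC103335842) from 2.3 ± 0.68 to 31.4 ± 2.33. WIN1 (LOC103342080), an ethylene-responsive-type factor of wax and cutin synthesis, rose from 1.61 ± 0.182 to 46.5 ± 25. Members higher and lower numbered 40 and 26 of 95 for auxin, 29 and 37 of 109 for ethylene, 8 and 8 of 24 for gibberellin, 7 and 5 of 24 for abscisic acid, 18 and 10 of 41 for jasmonate, 8 and 11 of 33 for cytokinin and 4 and 2 of 8 for brassinosteroid (67, 67, 17, 11, 28, 20 and 6 adjusted over the list alone). Among factors, NAC25 (LOC103338953) rose from 3.61 ± 1.02 to 52.7 ± 10.4 and CUP-SHAPED COTYLEDON 3 (LOC103336634) fell from 15.6 ± 2.02 to 5.07 ± 0.896, and the NAC list had 10 higher and 20 lower of 52. MADS-box factors were split, 11 higher and 11 lower of 31, with the SEPALLATA-type CMB1-like (LOC103338637) up from 27 ± 1.89 to 81.4 ± 12.2. Pistil and ovule development genes were higher in 8 and lower in 10 of 27 (30 NAC, 22 MADS-box and 19 pistil and ovule genes adjusted over the list alone). WUSCHEL-related homeobox 9 (LOC103325088) fell from 19.1 ± 2.18 to 4.05 ± 1.26. Heat shock genes were higher in 9 and lower in 26 of 63, pathogenesis-related genes in 44 and 30 of 108, senescence and cell death genes in 4 and 7 of 14 and autophagy genes in 5 and 5 of 22 (37, 76, 11 and 10 adjusted over the list alone). Ribosomal protein genes were higher in 53 and lower in 52 of 279, photosynthesis genes in 19 and 4 of 51 and aquaporins in 8 and 7 of 21 (87, 19 and 15 adjusted over the list alone). For ribosomal proteins the balance turned to 51 and 52 with equal sums and to 42 and 63 under quantile normalization, and the even split of gibberellin became 7 and 8 under all 3 other scalings. The camera adjusted p of the lists in this paragraph was 0.0863 or more.

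The limma test called 10234 genes (55.9%) between OVB and STIB, 4908 higher and 5326 lower. Of these, 1425 rose and 1848 fell by at least 1 on the log2 scale. The balance turned under quantile normalization (5420 higher, 5150 lower) and with array weights (6298 and 6248). Medians, means and camera directions differed in sign for gibberellin (0.145, -0.24, up), cytokinin (-0.11, 0.035, down) and ribosomal proteins (0.01, -0.03, up).

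From STYB to OVB the largest falls included MADS-box genes. AGL24-like (LOC103319497) went from 96.4 ± 62.1 to 0.2 ± 0.04 FPKM (log2 change -6.12), JOINTLESS-like (LOC103319503), of the same family, from 110.7 ± 72.6 to 0.917 ± 0.201, and CASP-like protein 1B1 (LOC103325315), of a family of membrane scaffold proteins, from 44.7 ± 14.45 to 0.627 ± 0.365. CYP86A1 (LOC103320591) fell from 162.2 ± 21.1 to 4.49 ± 1.12 and peroxidase-like protein 2 (LOC103335954) from 586.3 ± 33.4 to 18.6 ± 1.39. Rises included an endochitinase EP3-like gene (LOC103322384, a near copy), which breaks chitin, from 36.7 ± 52.1 to 1425 ± 265, 7-deoxyloganetin glucosyltransferase-like (LOC103321643) from 2.83 ± 2.65 to 313.4 ± 64, and the MYB gene LOC103329844 from 0.267 ± 0.085 to 146.5 ± 30.6. The STYB libraries 1, 2 and 3 differed widely for some of these genes, with 6.96, 6.25 and 96.77 for the endochitinase LOC103322384, 5.88, 1.55 and 1.06 for LOC103321643, 39.38, 162.65 and 87.27 for LOC103319497 and 40.37, 185.43 and 106.38 for LOC103319503. The limma adjusted p of these genes ran from 1.7e-07 for the MYB gene to 0.000388 for the endochitinase. Of 43 flavonoid genes 32 rose and 6 fell (38 adjusted over the list alone; camera adjusted p = 9.2e-05, and adjusted p = 0.69 with an estimated correlation). In it, LOC103332910 rose from 69.6 ± 2.49 to 588.2 ± 71.8. PMADS 2 (LOC103319765) and DEFICIENS (LOC103321303) rose from 618.9 ± 57.3 to 1211 ± 29.5 and from 24 ± 3.5 to 44.15 ± 2.92, and DEFICIENS-like (LOC103340165) stood at 383.9 ± 6.92 and 353.5 ± 3.22 (limma adjusted p = 0.303). The ratio of PMADS 2 to AGAMOUS was 18.3, 13.2 and 13.5 in the STYB libraries and 7.7, 9.9 and 8.4 in the OVB libraries. Antioxidant genes rose in 46 and fell in 11 of 86 (57 adjusted over the list alone; camera adjusted p = 0.00327, and adjusted p = 0.88 with an estimated correlation). Monothiol glutaredoxin-S10 (LOC103322936) rose from 0.25 ± 0.298 to 17 ± 4.29. DNA replication and histone genes fell in 41 and rose in 2 of 64 (45 adjusted over the list alone; camera adjusted p = 1.3e-09, and adjusted p = 0.88 with an estimated correlation). Cell cycle genes fell in 65 and rose in 11 of 112 (77 adjusted over the list alone; camera adjusted p = 4e-09, and adjusted p = 0.88 with an estimated correlation). Histone H2A variant 1 (LOC103334178) fell from 445.8 ± 79.6 to 154.3 ± 15.4, and kinesin-like protein KLP2 (LOC103339465), a spindle motor, from 5.38 ± 0.655 to 0.883 ± 0.372. WRKY factors fell in 26 and rose in 4 of 52 (30 adjusted over the list alone; camera adjusted p = 0.00327, and adjusted p = 0.88 with an estimated correlation). WRKY40 (LOC103320741), a defence-related factor, fell in this comparison from 190.9 ± 80.5 to 28 ± 5.69.

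A further 5 lists moved between STYB and OVB with camera adjusted p values closer to the threshold. Petal pigment markers rose in 9 and fell in 1 of 11 (10 adjusted over the list alone; camera adjusted p = 0.00743, and adjusted p = 0.88 with an estimated correlation). A bifunctional dihydroflavonol 4-reductase (LOC103320869), of anthocyanin synthesis, rose from 204.1 ± 24.6 to 459.9 ± 23.2 FPKM. These markers are also members of the flavonoid list. Starch and sugar breakdown genes rose in 21 and fell in 6 of 43 (29 adjusted over the list alone; camera adjusted p = 0.0483, and adjusted p = 0.88 with an estimated correlation). The risers there included alpha-amylase (LOC103320333), from 2.76 ± 0.779 to 52.9 ± 15.05, the wall invertase LOC103341755, from 0.183 ± 0.0764 to 219.8 ± 228.2, and both invertase inhibitors named above, which act against invertase. Sugar transport genes rose in 20 and fell in 7 of 40 (28 adjusted over the list alone; camera adjusted p = 0.0483, and adjusted p = 0.69 with an estimated correlation). Polyol transporter 6 (LOC103340061) rose from 0.357 ± 0.0643 to 11.4 ± 3.73. NAC factors fell in 22 and rose in 9 of 52 (32 adjusted over the list alone; camera adjusted p = 0.0483, and adjusted p = 0.88 with an estimated correlation). NAC92 (LOC103320136) fell from 17.3 ± 4.81 to 0.693 ± 0.381 and CUP-SHAPED COTYLEDON 1 (LOC103338789) from 12.6 ± 2.76 to 0.463 ± 0.189. Pistil and ovule development genes fell in 12 and rose in 3 of 27 (15 adjusted over the list alone; camera adjusted p = 0.0483, and adjusted p = 0.88 with an estimated correlation). YABBY 4-like (LOC103337233), of a family that sets organ polarity and carpel form, fell from 147.9 ± 29.4 to 19.7 ± 6.31, and SHI RELATED SEQUENCE 5 (LOC103321307), of a family that acts in style and stigma growth, from 25.8 ± 0.854 to 5.55 ± 1.55. CRABS CLAW (LOC103342035), a carpel development factor named here after its values were seen, rose from 97 ± 14.9 to 190.6 ± 56.1. Starch and sugar breakdown was no longer called without STYB replicate 1 (0.087), STIB replicate 3 (0.053), OVB replicate 1 (0.0607) or OVB replicate 3 (0.0517). Sugar transport was lost without STYB replicate 3 (0.0732), STIB replicate 3 (0.0529) or OVB replicate 1 (0.0742). NAC was lost without STYB replicate 2 (0.0778), STYB replicate 3 (0.0895), STIB replicate 3 (0.0529) or OVB replicate 1 (0.0527). Pistil and ovule development was lost without STYB replicate 1 (0.0559), STYB replicate 2 (0.0778), STIB replicate 3 (0.0529), OVB replicate 1 (0.0527) or OVB replicate 2 (0.0562). With a pseudocount of 0.1 starch and sugar breakdown, sugar transport and NAC stood at 0.0521 and pistil and ovule development at 0.0646, and NAC stood at 0.0522 under median ratio scaling.

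Other lists did not pass camera between STYB and OVB. ACC oxidase (LOC103329345) rose from 57.8 ± 7.29 to 504.1 ± 24.5 FPKM and WIN1 (LOC103342080) from 0.317 ± 0.262 to 46.5 ± 25, but the ethylene list had 29 higher and 46 lower of 109 (77 adjusted over the list alone; camera adjusted p = 0.0747). YUCCA4 (LOC103320034) fell from 7.96 ± 0.255 to 0.35 ± 0.13 and auxin response factor 9 (LOC103337763) from 36.2 ± 3.34 to 6.46 ± 0.879, in an auxin list of 36 higher and 36 lower of 95. Gibberellin 3-beta-dioxygenase 1-like (LOC103320029) fell from 67.8 ± 34.9 to 1.45 ± 0.155. Members higher and lower were 7 and 9 of 24 for gibberellin, 5 and 9 of 24 for abscisic acid, 19 and 9 of 41 for jasmonate, 7 and 12 of 33 for cytokinin and 3 and 2 of 8 for brassinosteroid (72 auxin, 17 gibberellin, 14 abscisic acid, 28 jasmonate, 20 cytokinin and 5 brassinosteroid genes adjusted over the list alone). Expansin-A8 (LOC103332890), a wall-loosening protein, rose from 7.56 ± 1.74 to 162 ± 86.7, in a wall loosening list of 7 higher and 15 lower of 37. Cellulose synthesis genes were higher in 9 and lower in 9 of 24, pectin degradation genes in 35 and 17 of 75, lignin and phenylpropanoid genes in 28 and 11 of 69, and peroxidases and polyphenol oxidases in 13 and 14 of 46 (22 wall loosening, 18 cellulose, 54 pectin, 39 lignin and 28 peroxidase or polyphenol oxidase genes adjusted over the list alone). Metacaspase-4 (LOC103325575), a cell death protease, rose from 31.1 ± 2.02 to 88.5 ± 10.6, and the senescence and cell death list had 8 higher and 2 lower of 14. Autophagy genes were higher in 3 and lower in 5 of 22, heat shock genes in 16 and 13 of 63, pathogenesis-related genes in 55 and 29 of 108, and cuticle and lipid genes in 25 and 41 of 106 (11 senescence, 8 autophagy, 29 heat shock, 87 pathogenesis-related and 69 cuticle genes adjusted over the list alone). MADS-box factors were higher in 11 and lower in 10 of 31, ribosomal proteins in 89 and 25 of 279, photosynthesis genes in 15 and 4 of 51 and aquaporins in 11 and 6 of 21 (22 MADS-box, 106 ribosomal, 16 photosynthesis and 17 aquaporin genes adjusted over the list alone). Under quantile normalization the balance turned for heat shock genes (15 and 17) and MADS-box factors (11 and 13, and 11 and 12 under median ratio scaling), and senescence and cell death genes counted 7 and 4. The even splits became 34 and 37 for auxin, 8 and 10 for cellulose synthesis and 4 and 5 for pollen and anther markers. Ribosomal proteins counted 74 and 33, photosynthesis genes 14 and 6, autophagy genes 2 and 6 and pistil and ovule genes 2 and 14, and the share of higher members was smaller in 30 of the 34 lists and larger in 0. Of the markers of other tissues, pollen and anther genes were higher in 4 and lower in 4 of 12, secondary wall and xylem genes in 10 and 6 of 21, and leaf and bract genes in 3 and 2 of 19 (8, 17 and 4 adjusted over the list alone). Fasciclin-like arabinogalactan protein 14 (LOC103319983) and pollen-specific leucine-rich repeat extensin-like protein 3 (LOC103335483) were listed at 0 in all STYB and STIB libraries. They stood at 66.07, 26.06 and 21.31 and at 52.13, 13.06 and 8.67 FPKM in OVB replicates 1, 2 and 3.

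**Figure D3:**
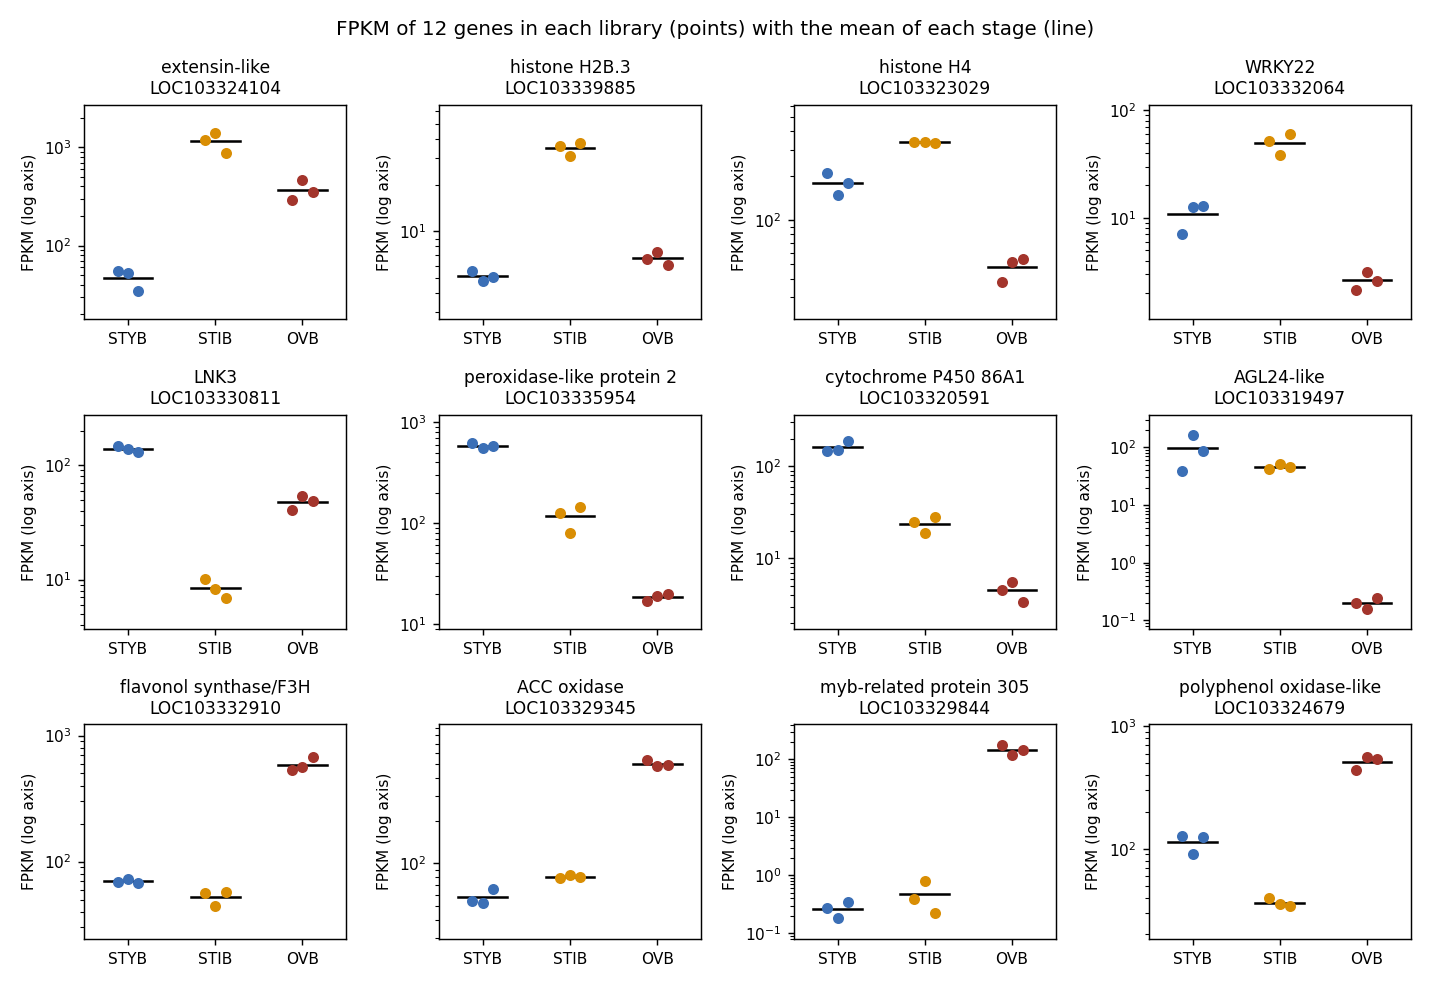
FPKM of 12 named genes at STYB, STIB and OVB on a log axis, with points for the 3 libraries of each stage and a line at the mean. Polyphenol oxidase-like LOC103324679 goes from 114.7 at STYB through 36.3 at STIB to 515.8 at OVB.

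Between OVB and STYB the limma test called 9520 genes (52%), 5163 higher and 4357 lower, of which 1610 rose and 1403 fell by at least 1 on the log2 scale. The balance turned under quantile normalization (4685 higher, 5139 lower) and without OVB replicate 2 (4198 and 4207). Medians, means and camera directions differed in sign for auxin (0.01, 0.145, down), gibberellin (0.02, -0.37, down), cellulose synthesis (0.045, 0.11, down), peroxidase and polyphenol oxidase (-0.08, 0.13, down), pollen and anther (-0.015, 0.43, up) and secondary wall markers (-0.04, 0.675, up). The self-incompatibility list had 0 tested members. Over the 3 comparisons, camera called 22 of 102 pairs of a list and a comparison. With an estimated correlation none of the 22 calls held, as camera called 0 pairs, with 2 pairs at an unadjusted p under 0.05. Fry, which tests a list by itself, called 10, 16 and 21 lists in the 3 comparisons.

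Many of the changes from STYB to STIB had the opposite direction from STIB to OVB. WRKY22 (LOC103332064), H2B.3 (LOC103339885) and the extensin-like gene (LOC103324104, 369.8 ± 88.2 FPKM at OVB) were highest at STIB, and CONSTANS-LIKE 2 (LOC103329622, 120.3 ± 23.6 at OVB) and B-box zinc finger protein 32 (LOC103327411, 80.8 ± 17 at OVB) were lowest there. Of the genes called by limma in both comparisons, 2497 rose and then fell where independent lists would share 1301, and 1573 fell and then rose where 817 would be shared. Genes with the same direction in both were fewer, 522 rising (1199 for independent lists) and 429 falling (887). Simulations in which all 9 libraries, STIB included, were drawn without a stage difference gave 0 shared calls in 20 simulations. Unchanged groups pass the threshold so rarely that this value does not measure the excess. The 3 STIB libraries enter both comparisons with opposite sign and could not be divided with at least 2 on each side, so part of the excess may come from these shared libraries.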

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

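The fits without near-copy genes, the list tests without each replicate and the list counts under each scaling were chosen only after the data were seen, and all other alternatives before. Of the counts of changed genes, only those under a minimum log2 change of 1 moved by over 1.5 times, to 1411 genes for STIB against STYB, 3273 for OVB against STIB and 3013 for OVB against STYB, because that setting asks for a size as well. Leaving out each replicate in turn called 5706 to 8189, 8550 to 10622 and 7756 to 9125 genes, with 0 genes called in the opposite direction. Of the 7522, 10234 and 9520 genes called with all libraries, as few as 5596, 8425 and 7649 were called again in the same direction. Under quantile normalization 6593, 9782 and 8992 of them were called again in the same direction. Without near-copy genes the counts were 6591, 8865 and 8308, and with array weights 8907, 12546 and 11130. Whether the replicate numbers pair the libraries is not settled. Same-numbered deviations correlated at -0.11 to 0.33, and 5 of 9 libraries had their highest correlation with their own replicate number in another stage. A block for the replicate number called 7476, 10218 and 9487 genes. Camera called 22 list-by-comparison pairs, 0 with an estimated correlation (2 at an unadjusted p under 0.05), 21 with the replicate block, 18 with a pseudocount of 0.1, 22 with median ratio scaling and 18 to 26 without a replicate, and fry called 47. Of the 22 pairs, fry kept 21, the block 21 (starch and sugar breakdown at 0.0566 in OVB against STYB), the pseudocount 18 and median ratio scaling 21, and the direction of all 22 held in these settings. The cause of these changes was not tested. Over the scalings, the balance of higher and lower members turned in 3, 1 and 2 of the 34 tested lists and the median in 4, 1 and 3, with camera calls in none of them. Of the medians, those of flavonoid, NAC, photosynthesis and cuticle and lipid genes turned in STIB against STYB, that of ribosomal proteins in OVB against STIB, and those of auxin, gibberellin and brassinosteroid genes in OVB against STYB. Named genes were chosen for large or clear changes in these same data, so the share of them that held is not that of all calls. Of 6940 values of named genes under alternatives, 6928 kept their direction and side of the threshold, 12 no longer passed and 0 reversed. Genes that missed the FPKM filter in a fit were not tested there and are not counted. Of 338 named results, 310 were tested without each OVB replicate, 335 without each STYB replicate and 317 with a filter of FPKM 5. Genes at FPKM 1 or more in the 3 OVB libraries alone were thus not tested without an OVB library. Of the 12, 11 were of LOC103334105 in STIB against STYB (adjusted p = 0.0487, and 0.0508 to 0.1545 in those settings), which stood at 51.72, 3.46 and 134.53 FPKM in the STIB libraries, and 1 was of LOC103320968 under quantile normalization (0.059). DESeq2 was not run, since the deposited table holds FPKM without counts. At the estimated depth, FPKM 1 in a transcript of 1 kb effective length rests on 23 to 26 fragments, so values below it rest on few fragments.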

Other observations

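The gene groups in this part, the tests of tapetum and clock genes and those of the depth and course of OVB replicate 1 were chosen only after the results were seen. The tests of other splits and of GC content and length were planned before, and the scaled form of the test of the course of OVB replicate 1 was added after its first result. Prunus tissues store cyanogenic glucosides. Of 9 genes of cyanide metabolism, 6 of them near copies and without a test of the group, 5 rose, 1 fell and 3 did not pass from STIB to OVB. From STYB to OVB 4 rose, 1 fell and 4 did not pass. (R)-mandelonitrile lyase 4 (LOC103323463), which releases hydrogen cyanide, went from 559.4 ± 83 FPKM at STYB through 991.7 ± 178 at STIB to 2628 ± 298 at OVB. L-3-cyanoalanine synthase 1 (LOC103342779), which detoxifies cyanide, stood at 201.1 ± 8.31, 203.3 ± 24.1 and 371.6 ± 9.41. Of 45 cold and dormancy genes, of which 8 are near copies and 8 are in the fixed lists, 29 fell and 9 rose from STYB to OVB (median log2 change -1.58). Galactinol synthase 1 (LOC103321778), of the synthesis of protective sugars, went from 67.7 ± 68.1 (26.69, 146.35 and 30.18 in the STYB libraries) through 14.1 ± 4.18 to 1.6 ± 0.689, whereas early light-induced protein 1 (LOC103323985), of light stress protection, went from 9.87 ± 5.97 through 34.5 ± 4.53 to 544.1 ± 63.9. Polyphenol oxidase genes, 8 in number, with 2 near copies and all in a fixed list, rose in 5 and fell in 0 from STYB to OVB and rose in 4 and fell in 0 from STIB to OVB. From STYB to STIB 0 rose and 1 fell. Of them, LOC103324683 stood at 60.4 ± 10.6, 48.3 ± 2.02 and 145.3 ± 14.2, and LOC103324714 at 37.6 ± 10.1, 34.5 ± 40 and 288 ± 44.4, with 80.58, 9.39 and 13.4 in the STIB libraries 1, 2 and 3.

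Most genes of the tapetum and of sporopollenin, the wall polymer of pollen, were highest at STIB. Of 18, with 6 near copies, 12 rose and 0 fell from STYB (median log2 change 2.5), and 12 fell and 3 rose from STIB to OVB. LOC103329851, LOC103330649 and LOC103330650 were highest at OVB, and LOC103330651 was lowest at STIB. At STYB, STIB and OVB, CYP704B1 (LOC103321679) stood at 0.877 ± 0.512, 12.8 ± 2.23 and 0.97 ± 0.793 FPKM and ABORTED MICROSPORES-like (LOC103334915) at 0.627 ± 0.0651, 8.59 ± 2.85 and 0.377 ± 0.311. The STIB libraries varied widely for some risers, with type III polyketide synthase A (LOC103331542) at 41.8 ± 47.3 there. Scaling of the libraries was argued against as the cause, since the median was 2.46 after median ratio scaling. Stamen or petal tissue beside the pistil may be present in every library, since the lowest ratio of PMADS 2, a gene of petals and stamens, to AGAMOUS was 7.7. Whether STIB held a larger share of stamen tissue stays open: the median log2 change of the 3 B-class genes from STYB to STIB was -0.03, with DEFICIENS-like (LOC103340165) down from 383.9 ± 6.92 to 217 ± 28, and from STIB to OVB all 3 rose (median 0.71) while the tapetum genes fell, but petals, which express them too, could hide a change. The stage of the flower buds differs between the groups by design and stays open as an untested biological explanation.

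Clock genes of the morning were lower at STIB: 8 of 11 fell and 0 rose from STYB (median log2 change -0.85). From STIB to OVB 6 of the 11 rose and 0 fell (median 0.39). From STYB to OVB 6 of the 11 fell and 1 rose, so that part of the genes stayed low at OVB. LHY (LOC103342352) stood at 101.3 ± 0.99, 38 ± 0.475 and 99.1 ± 23.5 FPKM at STYB, STIB and OVB and REVEILLE 8 (LOC103340488) at 21.6 ± 0.928, 11.52 ± 0.732 and 11.3 ± 2.6. Of 9 evening genes 3 rose and 3 fell from STYB to STIB. Among the risers was LUX (LOC103322087, from 7.65 ± 0.889 to 22.3 ± 0.839). Among those that fell were adagio protein 3 (LOC103320949, from 48.5 ± 2.28 to 16.8 ± 0.775) and PCL1 (LOC103342895, from 46.5 ± 8.51 to 25.9 ± 1.15). Scaling of the libraries was argued against, since the median of the morning genes was -0.9 after median ratio scaling. Another time of day of collection at STIB stays open: the medians of morning and evening genes differed by -1.09, but the genes were gathered after the fall of LNK3 was seen, they are regulated together, and the evening genes went both ways. A change of the clock with the stage itself would give the same values and was not tested apart.

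OVB replicate 1 stood apart from the other OVB libraries. Lower depth was argued against, since its estimated depth was 100.4% of the mean of the other 2. It nevertheless had 2045 listed genes at 0, against 1498 and 1540 in OVB replicates 2 and 3. Genes at FPKM 1 or more numbered 16882, against 17600 and 17507. The cause of these differences was not tested. A bias by GC content or transcript length stays undecided, with a larger rho of 0.12 (GC content 0.12, length -0.02), between the bounds set before. Whether this library lay further along the change from STIB to OVB stays undecided too: 58.3% of the called genes lay beyond the other 2 libraries in the direction of change, and its median difference was 0.04 in genes that rose and -0.08 in genes that fell after scaling, and as deposited -0.07 and -0.17, where that over all tested genes was -0.12. After scaling, and as deposited relative to the -0.12, these medians go in the direction of the change, but the scaled form was added after the first result, and the same share taken for OVB replicates 2 and 3, each against the other OVB libraries, was 27.3% and 45.2%.

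For the counts of changed genes, 1 of the 10 splits of the 6 libraries gave as many genes as the stages in each comparison, the real one. The real counts were 7522 for STIB against STYB, 10234 for OVB against STIB and 9520 for OVB against STYB, and the highest of the other splits by limma 0, 5 and 0 (580, 490 and 1113 at an unadjusted p under 0.05). These splits are too few for a share under 0.05. Each of the other splits also mixes libraries of both stages, so the stage difference enters the spread and lowers the calls. Their counts therefore do not measure what chance alone would give.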
